A study of Homo sapiens with 6 samples.

How the data were processed

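The data were RNA sequencing profiles of cultured human dermal fibroblasts, the CCD-1064Sk line (CRL-2076 of the American Type Culture Collection), a fibroblast line from skin. Cells had been made to carry short-hairpin RNAs, which direct the degradation of a matching transcript, either against the zinc-finger gene ZNF469 (shZNF469, 3 libraries) or as a control (shControl, 3 libraries). The labels describe the 3 libraries of each group as technical replicates. The p-values below therefore measure only the spread between these libraries and not that between independent cultures or hairpins. The hairpin sequences, and how many different hairpins were used, are not given in the sources used here.

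Total RNA was extracted on columns and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. HISAT2, StringTie and the GRCh38.p14 genome build are named, per the submitters' processing notes, without tool versions. The annotation release, the strand setting of the counting and any filter on low values are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and values of such genes are uncertain. The deposited table lists 21151 genes, with a whole-number count of reads per gene and library and, beside it, the TPM (a length-scaled transcript abundance) that the authors computed. Of these genes, 4195 have no symbol, and 58 symbols are listed more than once; for those the entry with the highest mean was used. A gene identifier of GENCODE release 29 matched 89.6% of the listed genes, and its records gave GC content, transcript length and overlaps between genes. Coordinates are those of RefSeq on GRCh38.p14.

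A listed value of 0 is not proof of absence of reads. The lowest TPM above 0 lay between 0.333 and 0.456 in the 6 libraries, and no smaller value above 0 is listed. No upper limit was therefore attached to a 0, and no fold change is given for a gene listed at 0 in all libraries of a group. Total counts ran from 35417366 to 48298264 per library. Within groups, log2 CPM (counts scaled to a common library total) of library pairs correlated with Pearson's r of 0.949 to 0.967 across genes, which are not independent replicates. The chi-square statistic of their counts was 8.57 to 38.9 per degree of freedom, above sampling noise in each pair, which argues only against a repeated deposit of one library and does not show that the libraries came from separate cultures.

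The count analysis used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by the trimmed mean of M-values (TMM), and the 2 groups were compared by the quasi-likelihood F-test (two-sided, no covariate) with Benjamini-Hochberg adjustment over the 16353 genes tested. A gene passed at an adjusted p under 0.05. Values given as CPM are TMM-scaled group means ± SD (n = 3), and the standard error (SE) of a log2 fold change was taken from the estimate and its F statistic. In all of these, a log2 fold change is shZNF469 minus shControl. On simulated counts for the 16353 genes of this comparison, with 200 genes changed, the test recovered 47% of 1.5-fold changes and 61% of 2-fold changes, and 6 of its 114 calls were unchanged genes. A change of those sizes can thus have been missed.

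The 32 gene lists, written out before the data were examined, covered matrix components, matrix turnover, signalling, proliferation, stress, metabolism, RNA quality and markers of other cell types. Members were counted as higher or lower by the adjusted p over all genes, and again adjusted over the list alone. Each list was set against all other genes by camera of limma 3.58.1, with its preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with a correlation estimated per list. With the estimated correlation, the calls of the cell cycle list and of the unfolded protein and integrated stress response list held, and those of the other 10 called lists did not. For matrix proteases, p53 targets, cholesterol synthesis and BMP and WNT genes the estimate was below the preset (-0.031 to -0.0061). A higher correlation thus does not account for the loss of those calls, and the 2 settings differ in more than the correlation. For the other lists that lost their call the estimate was above the preset, at 0.017 to 0.76. For these too, the part played by the correlation was not separated from the other differences between the settings.

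Genes were named by a rule also written before the data were examined. It took ZNF469, 11 genes chosen in advance (among them COL1A1, COL1A2, COL3A1, COL5A1, COL6A1, FN1, ACTA2, POSTN, TGFB1 and CCN2), and the 8 largest rises and 8 largest falls among genes that passed. Those 16 also needed a symbol, a mean of 10 CPM or more and no overlap between the groups' libraries. Last, it took up to 4 members of each list with the lowest p. The rule names more list members than are described below, and the described ones were picked for space after their values were seen; 2 genes that the rule names are not reported here.

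Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom, median-of-ratios scaling, library totals alone, no low-count filter, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, a test against a 2-fold change, and leaving out each library in turn. Where a call is said to be lost in a number of alternative settings, the test against a 2-fold change is not counted. Chosen after the data were seen were a test on genes above 0 in all 6 libraries, limma on log2(TPM + 1) of the deposited TPM, a fit of each library on GC content and transcript length, and thinning of all libraries to the smallest total. Levels of genes used to infer sex were left out of the named genes.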

Results

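The transcriptome of dermal fibroblasts carrying a control hairpin or hairpins against ZNF469 was profiled to learn how this zinc-finger gene affects production of extracellular matrix. There were 3 libraries per group. Total counts were 35417366, 46911355 and 38149616 in the shControl libraries and 46788609, 48298264 and 41318439 in the shZNF469 libraries. On the first principal component of log2 CPM, which held 30.5% of the variance, the controls lay at -55.8, -10.2 and -52.0 and the knockdown libraries at 39.1, 36.7 and 42.2.

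ZNF469 itself was lower in each knockdown library than in any control. The gene (ENSG00000225614, protein coding, chromosome 16, 88100931 to 88440753 on GRCh38.p14) had 1416, 2179 and 1494 counts in the controls and 1000, 906 and 750 in the knockdown. Normalised expression fell from 42.0 ± 3.70 CPM to 19.4 ± 1.77 CPM (SD, n = 3), which left 46.2% of the control level. The log2 fold change was -1.12 (SE 0.09, edgeR adjusted p = 0.000873). The authors' TPM gave 7.14 ± 0.822 in the controls and 3.24 ± 0.342 in the knockdown.

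Across the transcriptome, 745 of 16353 tested genes were higher and 874 were lower in shZNF469 at an adjusted p under 0.05. The 2 directions differed more among large changes. A fall of 2-fold or more was seen for 159 genes, of which 43 had a mean of 10 CPM or more and 38 belonged to the cell cycle list. A rise of 2-fold or more was seen for 69 genes, of which only 4 reached a mean of 10 CPM, 43 were listed at 0 in at least 1 library and 20 had no symbol. The groups did not overlap for 31.4% of tested genes, where chance gives 10%. The counts depended on the tool and on single libraries. DESeq2 called 1638 genes higher and 1642 lower. Leaving out 1 library moved the count of higher genes by over 1.5 times to 215, 332 and 267 without shControl replicate 1, 2 and 3, to 204 without shZNF469 replicate 1 and to 496 without shZNF469 replicate 3. The lower genes came to 333, 397 and 405 without each control and to 388 without shZNF469 replicate 1. For rises of 2-fold or more the counts were 41 without shControl replicate 1, 26 without shZNF469 replicate 1 and 42 without shZNF469 replicate 2.

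The largest falls among well-expressed genes were led by PSAT1, an enzyme of serine synthesis, which dropped from 31.3 ± 2.92 to 5.69 ± 0.132 CPM (5.49-fold lower, log2 fold change -2.46, SE 0.09, adjusted p = 5.80e-05). PHGDH, which starts that pathway, was 2.74-fold lower and the amino acid transporter gene SLC7A5 2.69-fold lower. COL1A1, the alpha-1 chain of type I collagen, was 3.37-fold lower. RGS4, a regulator of G-protein signalling, was 2.95-fold lower, and the DNA synthesis genes RRM2 and FEN1 were 2.78-fold and 2.74-fold lower. TUBA1B-AS1 was 4.48-fold lower but varied widely (103 ± 16.3 against 23.3 ± 18.4 CPM), and as an antisense gene counted without a stated strand its value is uncertain. The largest rises were smaller. ALS2CL rose 2.02-fold, PMEL 2.01-fold, the glycosyltransferase gene GALNT15 1.97-fold, RRAGD, which encodes a GTPase that acts at lysosomes, 1.85-fold, BAALC 1.83-fold and the chemokine gene CXCL14 1.74-fold. SLC9A3-AS1 (1.75-fold) and PCDHGA4 (1.74-fold) rose as well, but the first is antisense and the second shares exons with its gene cluster, so both are uncertain. The calls of TUBA1B-AS1 and PCDHGA4 were each lost in 5 alternative settings, with adjusted p up to 0.104 for TUBA1B-AS1 and 0.126 for PCDHGA4.

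**Figure D1:**
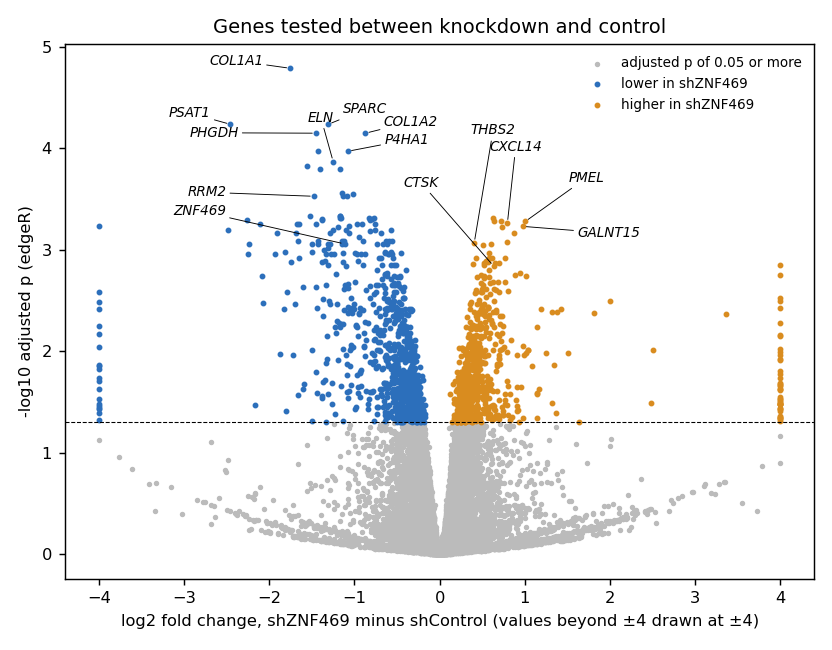
Each point is 1 of the 16353 tested genes, of which those used to infer sex are not drawn. The x axis gives the log2 fold change (shZNF469 minus shControl) and the y axis the negative log10 of the edgeR adjusted p. Points beyond 4 in either direction are drawn at 4, and the dashed line marks 0.05. COL1A1 has the smallest adjusted p (1.63e-05), and PSAT1 (log2 fold change -2.46) lies farther left than PMEL (1.01) lies right.

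Fibrillar collagen genes, which encode the main load-bearing collagens of skin, fell together. Of 8 tested members, 7 were lower and 0 higher, with a median log2 fold change of -0.63, and the counts were the same adjusted over the list alone. COL1A1 (chromosome 17, 50184101 to 50201631) had 20184, 21802 and 20423 CPM in the controls and 6521, 5904 and 6085 CPM in the knockdown (log2 fold change -1.75, SE 0.05, adjusted p = 1.63e-05). Its share of all counts went from 2.07 ± 0.101% to 0.618 ± 0.0282%. COL1A2 (chromosome 7, 94394895 to 94431227), the partner chain of type I collagen, fell less, by 1.83-fold (19409 ± 547 to 10622 ± 405 CPM, adjusted p = 7.09e-05). The ratio of COL1A1 to COL1A2 counts accordingly went from 1.07 ± 0.0182 to 0.581 ± 0.0144 without overlap between groups, where the smallest exact permutation p for 3 against 3 is 0.1. COL3A1 was 1.76-fold lower and COL5A1 1.43-fold lower. The camera adjusted p for the list was 4.87e-10, and the adjusted p = 0.174 with an estimated correlation.

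Other collagen genes moved less uniformly. Of 19 tested, 1 was higher and 3 lower (3 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.149), except without shControl replicate 3 (adjusted p = 0.0302). COL4A1, a basement membrane collagen gene, was 1.54-fold lower, COL15A1 1.51-fold lower and COL8A1 1.42-fold lower, while COL18A1 was 1.21-fold higher, a call lost in 10 of 17 alternative settings (adjusted p up to 0.151). COL6A1 was at 2997 ± 121 and 2707 ± 111 CPM and did not pass (adjusted p = 0.0846), although it did with DESeq2 (adjusted p = 0.0275) and after the GC content and length fit (adjusted p = 0.00465, the lowest of a range up to 0.335 over its alternatives). The call of COL8A1 was lost in 5 alternative settings. Left out singly, the 6 libraries gave 0 to 1 higher and 2 to 4 lower members of this list, and DESeq2 gave 3 and 6.

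**Figure D2:**
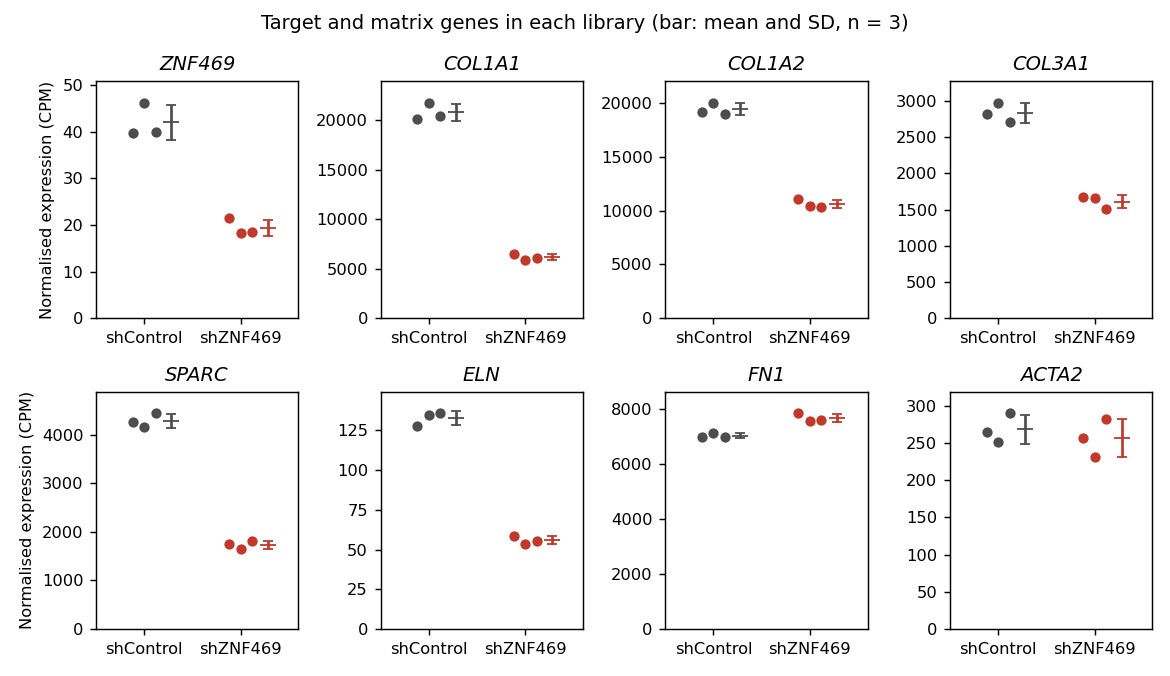
Normalised expression (CPM, y axes from 0) of ZNF469 and 7 matrix or contractile genes in each of the 3 shControl and 3 shZNF469 libraries (points), with the group mean and SD beside them. COL1A1 lies at 5904 to 6521 CPM in the knockdown against 20184 to 21802 CPM in the controls, while the ACTA2 values of the groups overlap.

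Genes that modify and assemble collagen were split. In the list of collagen folding, processing and cross-linking, 8 of 32 tested members were lower and 3 higher (10 and 6 adjusted over the list alone), and camera did not pass (adjusted p = 0.134). The falls included the prolyl hydroxylase genes P4HA1 (2.11-fold lower, 127 ± 0.438 to 60.3 ± 0.981 CPM) and P4HA2 (1.36-fold lower), the cross-linking enzyme gene LOXL2 (1.54-fold lower) and the collagen chaperone gene SERPINH1 (1.40-fold lower). Among elastic fibre and microfibril genes, 8 of 20 were higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.169, and 0.0237 without shZNF469 replicate 2). ELN, which encodes elastin, was 2.38-fold lower (133 ± 4.55 to 55.9 ± 2.47 CPM, adjusted p = 0.000135), whereas FBLN7, ADAMTSL4 and LTBP4 were 1.43-fold, 1.40-fold and 1.36-fold higher, the call of LTBP4 being lost in 2 of 17 alternative settings. Left out in turn, shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 left 0, 0, 0, 0, 5 and 0 higher and 5, 6, 8, 5, 8 and 7 lower collagen processing genes, and 2, 3, 2, 3, 9 and 4 higher and 1, 1, 1, 1, 2 and 1 lower elastic fibre genes.

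Of 41 matrix glycoprotein genes, 13 were higher and 5 lower (20 and 6 adjusted over the list alone), with a median log2 fold change of 0.13 and a camera adjusted p of 0.0182; the adjusted p = 0.237 with an estimated correlation, and 0.0608 without shZNF469 replicate 1. The member with the lowest p went the other way. SPARC, a collagen-binding glycoprotein gene, was 2.47-fold lower (4290 ± 141 to 1735 ± 86.6 CPM, adjusted p = 5.80e-05). POSTN (periostin) was 1.45-fold lower and NID2, of basement membranes, 1.38-fold lower. THBS2 was 1.33-fold higher (adjusted p = 0.000852). FN1, the fibronectin gene, was at 7025 ± 87.2 CPM in the controls and 7665 ± 153 CPM in the knockdown, a 1.09-fold rise (adjusted p = 0.0261) whose call was lost in 9 of 17 alternative settings (adjusted p up to 0.584). Of 26 proteoglycan and hyaluronan genes, 6 were higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.546). The hyaluronan synthase gene HAS2 was 2.05-fold lower, and the proteoglycan gene VCAN (versican) and the hyaluronan receptor gene CD44 were 1.63-fold and 1.25-fold higher. Without shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 in turn there were 1, 6, 3, 1, 11 and 7 higher and 4, 4, 4, 3, 4 and 4 lower matrix glycoprotein genes, so that the excess of higher genes was lost without shControl replicate 1 or 3 or shZNF469 replicate 1. For proteoglycan and hyaluronan genes there were 2, 4, 2, 2, 7 and 4 higher and 1, 2, 1, 1, 3 and 1 lower in the same order.

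Of 34 matrix protease genes tested, 9 were higher and 2 lower (11 and 4 adjusted over the list alone), with a median log2 fold change of 0.15 and a camera adjusted p of 0.00158; the adjusted p = 0.149 with an estimated correlation. CTSK, a collagen-degrading cathepsin gene, was 1.55-fold higher (1503 ± 105 to 2331 ± 120 CPM), CTSL 1.46-fold higher and MMP14, a membrane-bound collagenase gene, 1.28-fold higher. ADAMTS15 rose as well (log2 fold change 0.58). Among 18 protease inhibitor genes, 3 were higher and 3 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.586). PAPPA, which was in that list although its product is a protease, was 1.57-fold higher, TIMP3 1.26-fold lower and TIMP2 1.11-fold higher, and SERPINE2 was 1.13-fold lower. The calls of TIMP2 and SERPINE2 were lost in 8 and 10 of 17 alternative settings. The counts without 1 library, in the order of shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3, were 4, 6, 6, 5, 10 and 6 higher and 0, 1, 1, 1, 1 and 2 lower for matrix proteases, and 1, 1, 1, 1, 5 and 2 higher and 1, 1, 1, 1, 3 and 1 lower for protease inhibitors.

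**Figure D3:**
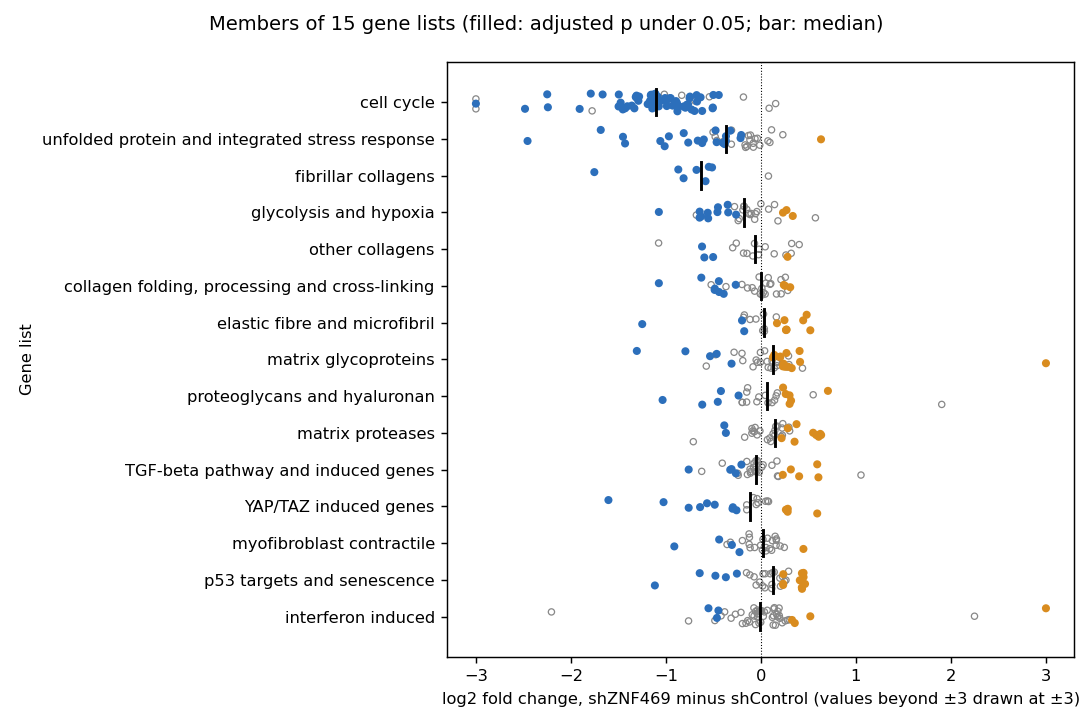
Each point is a tested member of 1 of 15 gene lists (y axis), placed by its log2 fold change, shZNF469 minus shControl, on the x axis, with values beyond 3 drawn at 3; filled points have an edgeR adjusted p under 0.05 (blue lower, orange higher) and the black bar is the list's median. The median is -1.10 for the cell cycle list and -0.63 for fibrillar collagens, and 0.13 for matrix glycoproteins and 0.15 for matrix proteases.

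Genes of the signalling pathways known to drive matrix production did not move as one. In the TGF-beta list, 5 of 34 members were higher and 5 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.586). CCN2, a matricellular growth factor gene, was 1.69-fold lower (169 ± 6.74 to 99.8 ± 2.68 CPM) and LMCD1 1.25-fold lower, while LRRC32 and TGFBI were 1.52-fold and 1.17-fold higher. TGFB1 itself was at 93.5 ± 4.43 and 86.8 ± 7.94 CPM (adjusted p = 0.476). Of 22 genes induced by YAP and TAZ, 9 were lower and 4 higher (11 and 4 adjusted over the list alone), with a median log2 fold change of -0.11 and a camera adjusted p of 0.00474; the adjusted p = 0.566 with an estimated correlation. CCN2 belongs to this list as well and had its lowest p, so its fall is counted in both lists. CCN1, F3 and FSTL1 were 1.40-fold, 1.56-fold and 1.48-fold lower. Of 22 BMP and WNT induced genes, 5 were higher and 1 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0208), and the adjusted p = 0.174 with an estimated correlation. APCDD1 rose (log2 fold change 0.58), AXIN2 was 1.30-fold higher and DKK1, a WNT inhibitor gene, was 1.22-fold lower. The calls of TGFBI, LMCD1, FSTL1, AXIN2 and DKK1 were lost in 4, 2, 1, 7 and 4 of 17 alternative settings. Left out in turn, shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 left 2, 1, 1, 3, 5 and 4 higher and 1, 2, 2, 2, 4 and 2 lower TGF-beta genes, 0, 1, 1, 1, 3 and 2 higher and 6, 7, 7, 7, 9 and 8 lower YAP and TAZ genes, and 2, 3, 2, 2, 4 and 3 higher and 0, 0, 0, 0, 1 and 1 lower BMP and WNT genes.

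Of 28 contractile genes of myofibroblasts tested, 1 was higher and 4 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.754). ACTA2, the smooth muscle actin gene used as the myofibroblast marker, was at 268 ± 19.6 CPM in the controls and 256 ± 25.6 CPM in the knockdown (adjusted p = 0.724). The collagen receptor gene ITGA11, which is counted in the integrin list too, was 1.88-fold lower and TPM1 1.24-fold lower. Of 18 integrin genes, 2 were higher and 3 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.967), with ITGA2, another collagen receptor gene, 2.11-fold lower and ITGB3 1.38-fold higher. The calls of TPM1 and ITGA2 were lost in 4 and 1 of 17 alternative settings. DESeq2 called 8 contractile genes higher and 8 lower, and 5 integrin genes higher and 5 lower. Without shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 in turn there were 0, 0, 0, 0, 2 and 1 higher and 2, 2, 2, 2, 5 and 4 lower contractile genes, and 1, 1, 1, 1, 3 and 1 higher and 2, 3, 3, 3, 4 and 3 lower integrin genes.

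Cell cycle genes had the lowest camera p of the 32 lists. Of 73 tested members, 63 were lower and 0 higher (69 and 0 adjusted over the list alone), and the median member was 2.15-fold lower (log2 fold change -1.10; camera adjusted p = 1.20e-51, and adjusted p = 0.00114 with an estimated correlation). The proliferation marker MKI67 fell from 33.2 ± 0.689 to 14.8 ± 0.541 CPM (2.25-fold lower, adjusted p = 0.000159). UHRF1 was 2.65-fold lower and CENPF, of the kinetochore, 2.12-fold lower. Of 35 p53 target and senescence genes, 10 were higher and 5 lower (13 and 5 adjusted over the list alone; median log2 fold change 0.12, camera adjusted p = 0.0123), and the adjusted p = 0.172 with an estimated correlation. The cyclin-dependent kinase inhibitor gene CDKN1A was 1.35-fold higher (475 ± 13.5 to 640 ± 24.2 CPM), SESN1 1.35-fold higher and the nuclear lamina gene LMNB1 2.17-fold lower. Left out in turn, shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 left 4, 2, 3, 2, 10 and 7 higher and 2, 2, 2, 2, 4 and 2 lower p53 target and senescence genes, so that the excess of higher genes was lost without shControl replicate 2 or shZNF469 replicate 1.

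Genes of the unfolded protein and integrated stress responses fell as a list. Of 44 tested, 22 were lower and 1 higher (28 and 1 adjusted over the list alone), with a median log2 fold change of -0.37, a camera adjusted p of 5.07e-15 and an adjusted p = 0.00983 with an estimated correlation. Its members with the lowest p were metabolic genes. Besides PSAT1, PHGDH and SLC7A5, the mitochondrial folate enzyme gene MTHFD2 was 2.02-fold lower (53.6 ± 0.802 to 26.5 ± 1.28 CPM). Of 33 glycolysis and hypoxia genes, 11 were lower and 3 higher (15 and 4 adjusted over the list alone; median log2 fold change -0.18, camera adjusted p = 3.43e-05), and the adjusted p = 0.172 with an estimated correlation. The member with the lowest p was P4HA1, which is counted in the collagen processing list too. The glycolytic enzyme genes LDHA, ENO1 and PGK1 were 1.56-fold, 1.56-fold and 1.47-fold lower. Of 25 cholesterol synthesis genes, 0 were higher and 2 were lower, among them ACAT2, by 1.37-fold (2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.172 with an estimated correlation). The counts without 1 library, in the order of shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3, were 15, 17, 15, 14, 21 and 20 lower and 1 higher in each fit for this stress response list, and 0, 1, 0, 0, 3 and 2 higher and 6, 7, 9, 10, 11 and 9 lower for glycolysis and hypoxia. Cholesterol synthesis genes gave 0 higher and 1 to 4 lower with single libraries left out, and 2 and 8 with DESeq2.

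Immune gene lists did not pass as lists. Of 54 interferon induced genes, 4 were higher and 3 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.728). HLA-E was 1.43-fold higher and IFIT1 1.47-fold lower, and HERC5 was listed at 0 in all 3 controls and at 0.958 ± 0.131 CPM in the knockdown, a call lost in 3 alternative settings. Of 35 inflammatory cytokine and NF-kB target genes, 2 were higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.586), with SOD2 1.62-fold higher and the chemokine gene CCL2 2.18-fold lower. In the interferon list the median log2 fold change was -0.01 and the mean 0.13, so these differed in sign. That mean includes the fitted value of HERC5, for which no fold change is given, and would be negative without it. Without shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 in turn there were 3, 3, 3, 2, 7 and 3 higher and 1, 2, 1, 1, 2 and 2 lower interferon induced genes, and 1, 1, 1, 1, 2 and 1 higher and 1, 1, 1, 1, 1 and 2 lower inflammatory genes.

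Lists bearing on RNA quality were examined beside these changes. The 13 mitochondrially encoded genes held 3.89 ± 0.164% of counts in the controls and 4.48 ± 0.243% in the knockdown, with 5 higher and 0 lower (6 and 0 adjusted over the list alone; median log2 fold change 0.21, camera adjusted p = 0.000101), and the adjusted p = 0.542 with an estimated correlation. MT-ND2 was 1.38-fold and MT-CYB 1.35-fold higher. MT-ATP6 and MT-ATP8 were each 1.48-fold higher, but these genes overlap and share reads. The call of MT-CYB was lost in 5 of 17 alternative settings. Of 25 immediate-early and heat-shock genes, 7 were lower and 1 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.00271 towards lower, and adjusted p = 0.256 with an estimated correlation). The median log2 fold change was -0.15 and the mean 0.07, of opposite sign. That mean includes the fitted value of FOSB, for which no fold change is given, and would be negative without it. EGR1 and FOSL1 were 2.32-fold and 1.54-fold lower, and FOSB was listed at 0 in all 3 controls and at 0.890 ± 0.176 CPM in the knockdown, a call lost in 3 alternative settings. Of 76 ribosomal protein genes and 14 histone genes, 0 passed in either direction, also adjusted over the list alone (camera adjusted p = 0.705 and 0.447). The camera result for ribosomal proteins rested on single libraries: it pointed higher without shControl replicate 3 (adjusted p = 4.92e-05) and without shZNF469 replicate 2 (adjusted p = 0.00685), and lower without shZNF469 replicate 3 (adjusted p = 0.00250), in a range up to 0.749 over its alternatives. Left out in turn, shControl replicates 1, 2 and 3 and shZNF469 replicates 1, 2 and 3 left 3, 3, 3, 3, 7 and 3 mitochondrially encoded genes higher and 0 lower in each fit, and 1, 1, 1, 0, 1 and 1 higher and 2, 2, 2, 2, 6 and 5 lower immediate-early and heat-shock genes. In the histone list 1 gene was higher without shControl replicate 1 and 1 lower without shZNF469 replicate 3.

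No list of markers of other cell types passed in the main test, and the melanocyte list passed in 5 alternatives. Of 8 keratinocyte markers, DSP was 1.20-fold higher and KRT10 1.42-fold lower (the same count adjusted over the list alone; camera adjusted p = 0.967). Of 4 melanocyte markers, PMEL was higher, while MITF (50.8 ± 1.12 and 55.9 ± 6.42 CPM, adjusted p = 0.381) and KIT (58.3 ± 1.82 and 67.5 ± 3.13 CPM, adjusted p = 0.0627) did not pass; adjusted over the list alone 2 were higher (camera adjusted p = 0.0601). The melanocyte list passed camera, towards higher, with the replicate block (adjusted p = 0.0270), 1 CPM in at least 3 libraries (0.0142), no low-count filter (0.0499), genes above 0 in all libraries (0.00946) and without shZNF469 replicate 3 (0.0189), in a range up to 0.121 over its alternatives with the preset correlation. FLT1 was the 1 lower of 5 endothelial markers (1.31-fold lower, 1 lower adjusted over the list alone; camera adjusted p = 0.705) and MCAM the 1 lower of 12 pericyte and smooth muscle markers (1.25-fold lower, 3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.341). None of 6 haematopoietic markers passed, also adjusted over the list alone (camera adjusted p = 0.281). Of 21 fibroblast identity genes, 3 were higher and 3 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.546), with DPP4 and LRP1 1.40-fold and 1.31-fold higher. The members with the lowest p were COL1A1 and COL1A2, which also belong to the fibrillar collagen list and were lower (log2 fold change -1.75 and -0.87). Among these markers the calls of DSP, KRT10, MCAM and LRP1 were lost in 7, 3, 4 and 1 of 17 alternative settings, and KIT passed in 5. Left out singly, the 6 libraries gave 0 to 1 lower pericyte and smooth muscle markers, 0 to 1 higher haematopoietic markers, 0 to 1 higher and 0 to 1 lower keratinocyte markers, and 2 to 5 higher and 2 lower fibroblast identity genes; DESeq2 called 3 pericyte and smooth muscle markers higher and 4 lower, and 1 haematopoietic marker higher.

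Genes of alternative mesenchymal fates changed singly. Of 18 adipogenic genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.169), with APOE 1.34-fold and PPARG 1.23-fold higher and the fatty acid desaturase gene SCD 1.51-fold lower. Of 12 chondro-osteogenic genes, ALPL was 1.35-fold higher and MGP, ACAN and COMP were 1.73-fold, 1.34-fold and 1.24-fold lower (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.705). Left out singly, the 6 libraries gave 0 to 2 higher and 1 lower adipogenic genes, and 0 to 1 higher and 0 to 1 lower chondro-osteogenic genes. The calls of PPARG, ACAN, COMP, APOE, ALPL and MGP were lost in 8, 8, 7, 5, 2 and 2 of 17 alternative settings. The median and mean log2 fold change also differed in sign, without a camera call, for collagen processing (0.0016 and -0.10), contractile genes (0.02 and -0.04), integrins (0.0061 and -0.07) and fibroblast identity (0.08 and -0.05). For endothelial markers both were above 0 (0.27 and 0.17) while camera pointed lower.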

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

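The tests on genes above 0 in all 6 libraries, on log2(TPM + 1), after the GC content and length fit and after thinning were chosen after the data were seen; the others were planned. Against 745 higher and 874 lower genes, DESeq2 called 1638 and 1642, and limma on log2(TPM + 1) called 233 and 526, with 16 and 96 changed by 2-fold or more against 69 and 159. Of the 1619 calls, DESeq2 shared 97.0% and the TPM test 40.7%. The GC content and length fit called 1326 genes lower. With 1 CPM in at least 3 libraries, 39 genes rose by 2-fold or more; that filter removed low genes. A test against a 2-fold change left 5 higher and 22 lower, as it asks for more than an estimate past that size. Except for the test against a 2-fold change, the causes were not tested. Limma-voom, median-of-ratios scaling, library totals alone, no low-count filter, genes above 0 in all libraries and thinning kept the 4 counts within 1.5 times. Leaving out 1 library gave 204 to 769 higher and 333 to 854 lower genes, 26 to 87 and 116 to 177 changed by 2-fold or more, 11 to 14 gene lists, and 14 to 21 lower members of the unfolded protein and integrated stress response list (14 without shZNF469 replicate 1); each such fit has fewer samples. Counts of other lists moved too: higher members ranged from 1 to 11 for matrix glycoproteins, 2 to 10 for p53 targets, 2 to 9 for elastic fibre genes and 4 to 10 for matrix proteases. Over all settings, 277 of these other counts moved by over 1.5 times, or from 0 to any other count, and 758 did not. The test against a 2-fold change kept 1 of 7 lower fibrillar collagens, 6 of 63 lower cell cycle genes and 8 of the named genes. The fibrillar collagen count was 7 lower in each of the 17 other settings, and 51 to 63 cell cycle genes were lower with 1 library left out. Camera with an estimated correlation called 2 lists against 12.

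The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.02, 0.08 and 0.03. With the replicate block, 592 genes were higher and 736 lower, and 32 rose by 2-fold or more.

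Of 103 named genes, 98 passed, and 70 of these kept their call in each of those 17 settings that tested them. ACTA2, which did not pass, ranged from -0.14 to 0.011 with 1 library left out, and its sign changed without shZNF469 replicate 2 (0.011). That change is within its SE. Total counts of 35417366 to 48298264 leave genes near the lowest listed values with the least precision.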

Other observations

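The comparison with other matrix genes, the tests on genes listed at 0 and the corrections for GC content, length, depth and abundant genes were chosen after the results they bear on had been seen, and so were the 3 gene lists below. An interval given with a median is a 95% bootstrap interval, made by resampling the genes with replacement. It treats genes as independent and holds no spread between libraries or cultures.

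The unfolded protein and integrated stress response list was looked at through 2 lists made from its members. The amino acid and one-carbon list was made after PSAT1, PHGDH, SLC7A5 and MTHFD2 had been seen to fall, so these 4 were left out of its test, a restriction added after a first run with them. Of the other 7 genes, 4 were lower, with a median log2 fold change of -0.50 (95% interval -0.66 to -0.08). Of 17 endoplasmic reticulum folding and degradation genes, 7 were lower and 0 higher, with a median of -0.21 (-0.38 to -0.12). The means of the 2 lists differed by -0.25 (permutation test over members, two-sided, p = 0.0348, unadjusted; genes are not independent replicates). Both intervals span the bounds set, so whether one part of the list carries its fall is left open.

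RRAGD, PMEL, CTSK and CTSL, all higher in shZNF469, encode proteins of lysosomes or related organelles. This led to a list of 48 lysosomal genes that left out genes of the 32 lists and genes already seen. CTSB was removed after a first run because its values had been seen too. The median log2 fold change was 0.17 (95% interval 0.11 to 0.25), past the bound of 0.15 set beforehand but close to it, and 15 genes were higher and 0 lower (camera p = 6.53e-10, and p = 0.0272 with an estimated correlation). It was 1 of 3 lists made after seeing the data, and these p-values are unadjusted. A small general rise of lysosomal genes may therefore accompany the knockdown; a difference in growth of the cultures was not separated from it.

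The fall of the cell cycle list (63 of 73 genes, median -1.10) was weighed against technical causes. Were a GC content or length bias the cause, the fall should have shrunk after fitting each library on both. The median stayed at -1.09 (-1.15 to -0.95). Thinning all libraries to the smallest total left -1.08. Random thinning followed by scaling keeps the expected fold changes, so this step could not decide whether depth played a part. On simulated data, the fit removed all 3298 calls made by a GC trend. No length trend was simulated, so removal of a length bias by the fit was not checked. A difference in proliferation between the cultures is a candidate explanation. Whether it came from loss of ZNF469, an off-target effect of the hairpins or the density at harvest remains open, since the design has 1 control and 1 knockdown group.

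The fall of fibrillar collagens held after the GC content and length fit (median -0.73, interval -0.88 to -0.62) and with libraries scaled by all genes other than the 50 most abundant (-0.64). The 138 tested members of the other matrix lists went both ways, with 31 higher and 24 lower and a median of 0.038. The middle 95% of them (-1.06 to 0.54) spans the fibrillar collagen median of -0.63, so the test was undecided by the bounds set. The median and the 31 higher genes show only that these genes did not all fall in the full set of libraries. Among collagen processing, elastic fibre and matrix glycoprotein genes, most calls of higher genes were lost without some single libraries. The balance of higher and lower genes therefore does not decide whether matrix genes fell in general. The 24 lower genes show that part of the other matrix genes fell too, and whether they share a cause with the fibrillar collagens was not tested. Off-target effects and the lower cell cycle expression also remain open and were not tested.

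Among tested genes, 150 were listed at 0 in at least 1 library and at 100 counts or more in another. Those with coordinates overlapped another listed gene in 58.2% of cases against 46.4% of other tested genes (odds ratio 1.61, 95% interval 1.13 to 2.32, Fisher's exact test, p = 0.00686), so reads assigned to one gene or its neighbour may contribute. Their TPM where above 0 was a median of 3.31 times the lowest TPM of the library (2.64 to 4.18), between the bounds set for a minimum coverage, which is left open. Of the 150 genes, 9 were called; no biological explanation was tested.

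The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 745 higher and 874 lower genes and 69 and 159 changed by 2-fold or more, where the highest count of any other split was 1 for each, taking the larger direction. It called 12 gene lists, and the highest other split called 6. The cell cycle list and the unfolded protein and integrated stress response list were called in 9 of 9 other splits, ribosomal proteins in 5 and mitochondrially encoded genes in 3. Fibrillar collagens and immediate-early and heat-shock genes were called in 2 each. Glycolysis and hypoxia, YAP and TAZ, elastic fibre and other collagen genes were called in 1 each. Each other split sets 2 libraries of one group with 1 of the other, so part of the real difference remains in it. That difference also widens the spread within its groups, so its low gene counts do not measure what chance gives. Ribosomal proteins did not differ in the real split (camera adjusted p = 0.705), and their members moved together (estimated correlation 0.929). Their calls in other splits thus reflect differences between single libraries.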
